A study of Arabidopsis thaliana with 9 samples.

How the data were processed

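Transcript levels were measured on Affymetrix expression arrays in whole Arabidopsis thaliana seedlings (root, hypocotyl and cotyledons) of 3 genotypes: the Col-0 wild type and the hemera mutants hmr-5 and hmr-22. There were 3 arrays per genotype and 9 in all. Per the labels' protocols, seeds were kept in the dark at 4 °C for 4 days, then grown for 4 days at 21 °C in constant red light of 10 µmol per square metre per second on medium without sucrose, and biotin-labelled RNA was hybridised by the maker's standard procedure. The group and replicate number of each array were taken from the labels. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

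The deposited table holds 1 signal intensity per probe set and array on a linear scale. Per the submitters' processing notes the values were made with RMA, with no version given, but RMA returns log2 values and the deposited intensity values run from 0.0633 to 42335. After leaving out 2% of the probe sets at each end, the mean intensity of every array lies between 500.038 and 500.044. The deposited values were therefore scaled per array to a common trimmed mean of about 500, and the method behind them is not settled by the sources used here. The analysis plan had assumed log2 values and provided for log2 of the values if the table proved linear, which was done.

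Array medians ranged from 180.7 to 210.7 signal units, and 14.5% to 16.7% of probe sets lay under 32 units. No detection calls were used. A floor of 32 units, 5 on the log2 scale, was set from the planned filter. The highest control probe set for a spike that was not added lay between 18.9 and 37.0 units, over the floor on some arrays. A mean just over the floor may therefore still be background, and small folds from such means are uncertain. Where the lower group's mean was under the floor, a fold is given as "at least", from the brighter group's mean against the mean of the higher of floor and signal on each dim array; where both means were under it, no fold is given. Below a mean of 5 the median SD within genotypes was 1.06 on the log2 scale, against 0.15 above a mean of 10, so dim probe sets were measured much less precisely. The number of arrays limits the precision.

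Of 22810 probe sets, 64 controls were left out and 22746 were tested. The platform's gene table names a single gene for 13513 of these and several genes for 503, and leaves 8730 unnamed here. Of the single-gene probe sets, 1580 carry a symbol other than the locus code and 11933 a locus code only. Names were updated through the gene identifiers of the TAIR10.1 reference table, which matched 13436 probe sets, and 77 kept the platform's own symbol. A probe set of several genes entered a gene list only where all of its genes belong to that list.

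Log2 values were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), as a group-means model over all 9 arrays with empirical Bayes moderation. No filter was applied, and p-values were two-sided and adjusted by Benjamini-Hochberg over all 22746 probe sets for each of 3 comparisons, at a threshold of 0.05. A second count also asked for a fold of at least 2, which is 1 on the log2 scale. A moderated F test covered the 3 genotypes together. Tables and figures were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Every error written ± beside a log2 fold change is the standard error from the limma fit, with n = 3 arrays per genotype.

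Before the data were examined, 21 gene lists, the test design and the rule for named genes were fixed. The rule takes the 10 largest rises and 10 largest falls in each mutant (5 and 5 between mutants) among probe sets past the threshold with a single gene that has a symbol, and no overlap between the groups' arrays. It adds for each list up to 4 members with the largest change past the threshold, or the largest 2 where none passes, and a fixed set of light-response and plastid genes where measured. Genes known by a locus code only, 2 rises and 2 falls per comparison among those with both means above the floor, were chosen after their values were seen. Of 461 list genes, 127 were named in the gene table used, which leaves 8730 probe sets unnamed, so several lists rest on few members. A gene with several probe sets is represented by the brightest. Lists with at least 3 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison.

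Whether the replicate numbers pair the arrays was checked from the deviations of each array from its genotype's mean. On the brighter probe sets (mean at or above the median), same-numbered arrays of different genotypes correlated at 0.161 to 0.471, and arrays with different numbers at -0.386 to 0.175. By the mean over partners all 9 arrays correlated best with their own number, but taken singly hmr-5 replicate 2 correlated best with hmr-22 replicate 1 (0.175). Over all probe sets, where noise of dim probe sets dominates, same-numbered arrays correlated at 0.0179 to 0.0624. The numbers were taken to pair the arrays from the values on the brighter probe sets, a subset chosen after the data were seen, and the labels say nothing of a shared batch. The main fit does not use the pairing, which enters an alternative fit as a block.

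The fit was tested on simulated data of 22746 probe sets with planted changes for the comparison of hmr-5 with wild type. It recovered 5.97% of 67 probe sets changed 1.5-fold, 41.8% of 67 changed 2-fold and 62.1% of 66 changed 4-fold. There were 4 false calls among 22546 unchanged probe sets. Among the brighter probe sets the recovered shares were 8.57%, 63.9% and 94.1%. Far fewer probe sets were changed than the 27.6% called in hmr-5, which makes the adjustment stricter. The recovered shares therefore do not give the sensitivity of the real comparison. Alternatives were the replicate number as a block, an intensity trend, robust moderation, only the 2 genotypes compared, quantile normalization, centring on the median or the 75th percentile, 2 filters on dim probe sets, no suffixed probe sets, array weights, a minimum fold of 1.2, other list tests, and each array left out in turn. A scale of log2 of the signal plus 32 was added after the data were seen.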

Results

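Transcript levels of 22746 probe sets were compared between Col-0 wild type seedlings and 2 mutants of HEMERA (HMR), hmr-5 and hmr-22, after 4 days in constant red light, with 3 arrays per genotype. HMR, also called pTAC12, acts in phytochrome signalling and is part of the plastid-encoded RNA polymerase complex. The comparisons ask which transcripts change when HMR is mutated, and whether both alleles change them alike. No probe set is named for HMR in the gene table used here, so its own level could not be used to check the labels. Array medians lay between 180.7 and 210.7 signal units. The first principal component of the brighter probe sets carried 66.3% of the variance and placed the wild type arrays at one end, hmr-5 at the other and hmr-22 between them.

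In hmr-5 the signals of the plastid genome's transcripts moved in opposite directions. How far the labelling captured plastid RNA in each genotype was not tested. Of 27 plastid genes for photosystems, the cytochrome b6f complex and rbcL, 15 fell and 2 rose against wild type. The largest falls were in psbC (-3.79 ± 0.21 on the log2 scale, adjusted p 0.000195), psbA (-3.53 ± 0.30, 0.000422), psbB (-3.40 ± 0.22) and rbcL (-3.30 ± 0.14, 0.000135), followed by psbD (-3.18 ± 0.24), psbZ (-2.89 ± 0.16) and psbH (-2.87 ± 0.10). These encode photosystem II subunits, and rbcL encodes the large subunit of Rubisco. By contrast, 15 of 22 plastid polymerase, ribosome and housekeeping genes rose, led by the RNA polymerase subunit genes rpoB (2.82 ± 0.19, adjusted p 0.000231) and rpoC1 (2.63 ± 0.21, 0.000317) and the ribosomal protein genes rps15 (2.62 ± 0.19) and rpl20 (2.57 ± 0.24). The wild type values of rpoB, 5.03 to 5.55 on the log2 scale, lie near the floor of 5 and may be background. The size and rank of its rise are therefore uncertain. A single member of that list, rpl33, fell.

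**Figure D1:**
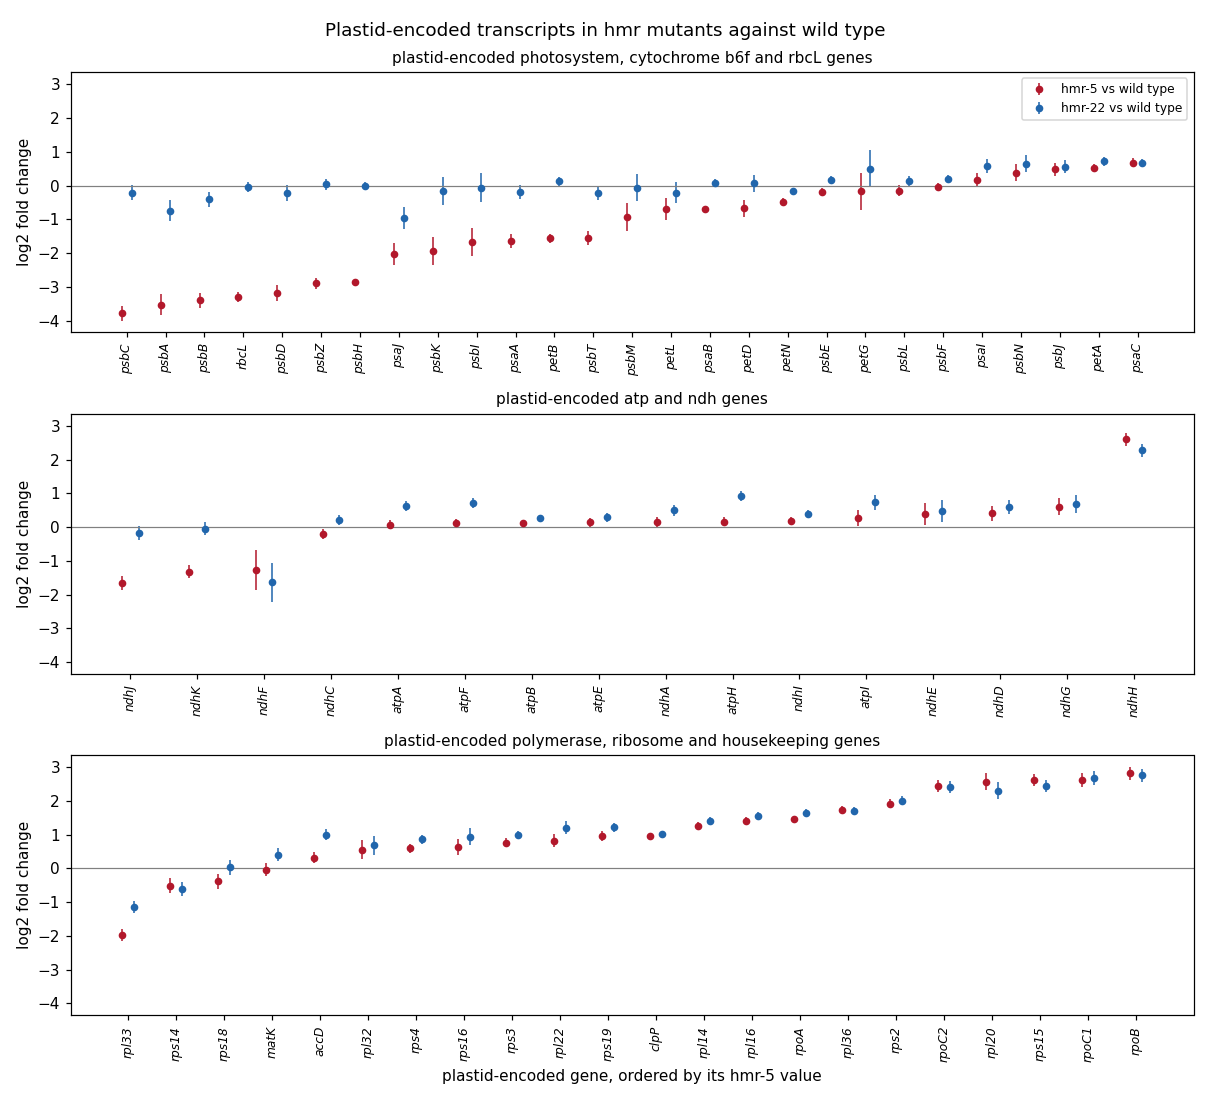
Log2 fold change against wild type (points) with its standard error (bars) of each measured member of the plastid gene lists, in hmr-5 and hmr-22, grouped by gene list and ordered by the hmr-5 value. Photosystem genes such as psbC lie at -3.79 in hmr-5 and -0.20 in hmr-22, while rpoB lies at 2.82 and 2.76.

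Adjusted over the list alone, 16 photosystem, cytochrome and rbcL genes fell and 3 rose, and 16 polymerase and ribosome genes rose and 1 fell. The list medians were -0.93 and 0.97, with camera adjusted p of 1.25e-05 and 4.3e-09. Both calls ended with an estimated inter-gene correlation (adjusted p = 0.375 for each with an estimated correlation). With that setting no list passed in any comparison, so it does not set these lists apart from others. Fry, which tests a list by itself and not against other genes, gave adjusted p 6.55e-05 for each. Among 16 plastid atp and ndh genes, ndhH rose (2.60 ± 0.19, adjusted p 0.000271), ndhJ (-1.66 ± 0.21) and ndhK (-1.32 ± 0.19) fell, and the list as a whole did not pass camera (adjusted p 0.419). Adjusted over the list alone the counts were the same, 1 and 2.

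Among nuclear genes for photosynthesis, none of 3 measured light-harvesting genes passed the threshold in hmr-5, over all probe sets or adjusted over the list alone, with LHCB4.2 at 0.23 ± 0.11 and LHCB4.3 at -0.15 ± 0.10. The LHCB4.3 value turns positive under quantile normalization (0.017) and median centring (0.031). LHCB4.2 passed once arrays were centred on their medians (adjusted p 0.0275). The 3 measured genes are all LHCB4 genes, of 20 genes in the list, and do not speak for the unmeasured ones. Of 8 other nuclear photosynthesis genes, SBPASE of the Calvin cycle fell (-0.81 ± 0.17, adjusted p 0.0102), with the same count adjusted over the list alone, and 6 of the 8 fell under quantile normalization. Of 9 chlorophyll and tetrapyrrole synthesis genes, 4 fell by both adjustments: GSA1 (-0.94 ± 0.16), PORB (-0.92 ± 0.12), HEME2 (-0.91 ± 0.15) and HEMB1 (-0.65 ± 0.12). Neither list passed camera (adjusted p 0.223 and 0.0595), although both did under quantile normalization (0.00837 each) and the tetrapyrrole list without wild type replicate 3 (0.0166). On the deposited scaling with all arrays they stood further from the threshold once the correlation was estimated (adjusted p = 0.663 and 0.438 with an estimated correlation). Of the nuclear genes of the plastid transcription machinery, 2 were measured and MRL7-L fell (-1.30 ± 0.18, adjusted p 0.00209), also adjusted over the list alone.

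Of 5 measured genes that phytochrome-interacting factors (PIFs) are known to induce, 3 fell, by both adjustments: the expansin gene EXPA8 (-2.25 ± 0.20, adjusted p 0.000479), the auxin-response gene IAA29 (-2.05 ± 0.28, 0.00193) and HAT2 (-1.51 ± 0.24, 0.00324). The list's median was -1.51 and its camera adjusted p 0.0268, which rose to 0.058 without wild type replicate 2 and to 0.0549 without hmr-5 replicate 1 (adjusted p = 0.375 with an estimated correlation). Of 8 cell wall expansion genes, 5 fell (3 with median centring) and EXPA4 rose (1.54 ± 0.20) by both adjustments, with XTH19 at -2.06 ± 0.43 and XTH16 at -1.58 ± 0.23 among the falls, and camera gave adjusted p 0.223. Auxin-inducible genes did not move together: IAA29 fell, IAA20 rose (1.71 ± 0.26), and WES1 rose by 0.37 ± 0.11 with adjusted p 0.0461, a call lost in all 9 fits that leave out an array, under quantile normalization (0.0562) and with only the 2 genotypes fitted (0.0899). The counts of this list were 2 rises and 1 fall by both adjustments and camera gave 0.608. Wild type values of IAA20, 5.03 to 5.47 on the log2 scale, lie near the floor of 5, so the size of its rise is uncertain. The endoglucanase gene GH9B8 (AT2G32990, -2.99 ± 0.19) had the largest fall of the named nuclear genes with a symbol and both means above the floor. CYP718 was at least 2.1-fold lower and TBL41 at least 3.2-fold lower than wild type; the TBL41 adjusted p of 0.0447 rose to 0.0647 with the replicate number as a block, 0.0703 with only the 2 genotypes, 0.0572 with quantile normalization, 0.0548 with median centring and 0.0593 with array weights, and 7 of the 9 fits that leave out an array lost it (0.0505 to 0.104).

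Both measured members of the carbon starvation list rose, by both adjustments: MCCA (AT1G03090, 2.68 ± 0.24, adjusted p 0.000479) and IVD (AT3G45300, 2.22 ± 0.15, 0.000237), which act in leucine breakdown. The isocitrate lyase gene ICL of the glyoxylate cycle (AT3G21720) rose most of the named genes with a symbol (2.96 ± 0.31, adjusted p 0.000805), and COR27 (2.76 ± 0.32), QQS (2.68 ± 0.24) and ATL8 (2.65 ± 0.17) rose too. The clock gene GI rose (1.21 ± 0.14), as did the gibberellin receptor genes GID1A (1.19 ± 0.12) and GID1B (1.14 ± 0.16), in each case also adjusted over the list alone.

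Remaining lists held few measured genes. STZ rose (1.11 ± 0.19) as the only call among 4 oxidative stress genes by both adjustments, and camera gave adjusted p 0.886. Both measured cell division genes fell, AUR2 (-1.01 ± 0.19) and AUR1 (-0.91 ± 0.17), by both adjustments. Of 3 root marker genes EXPA7 (-1.09 ± 0.28) and EXPA18 (-0.88 ± 0.22) fell by both adjustments, each losing its call in 4 of the 9 fits that leave out an array and with a minimum fold of 1.2, and camera gave 0.223. Nothing passed among 3 stomatal genes (SPCH -0.46 ± 0.26; for MUTE wild type was at least 1.42-fold higher; camera 0.419), 3 flavonoid genes (camera 0.918, with DFR at least 1.28-fold higher and no fold for AT4G14090, both means of which were under the floor), the light-signalling gene HYH (-0.10 ± 0.18), PDF1.2b (-0.07 ± 0.34) and PDF1.2 of the defence list (both means under the floor), or OLEO3 of the seed list (-0.83 ± 0.32, adjusted p 0.0941), which passed adjusted over the list alone, where it stood by itself. Among genes known by a locus code only, chosen after their values were seen, AT4G36430 (4.31 ± 0.16) and AT1G19540 (4.09 ± 0.22) rose, and AT5G12940 (-3.24 ± 0.73) and AT5G50740 (-3.09 ± 0.24) fell.

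Across all probe sets limma called 6286 between hmr-5 and wild type, 27.6% of those tested, of which 2608 were higher and 3678 lower; 2290 also passed 2-fold, 904 higher and 1386 lower. The balance of directions depends on scaling: with arrays centred on their medians 3966 were higher and 2480 lower, or 61.5% higher against 41.5%, and the median fold change of all probe sets shifted by 0.18. The share was 48.9% with quantile normalization and 45.1% with centring on the 75th percentile. A minimum fold of 1.2 left 3374 and ended the calls of TBL41, WES1, EXPA7 and EXPA18 among those named for this comparison (0.0663 to 0.465). It also ended those of ECS1 (0.0647) and petA (0.138), which were named for another comparison. The brighter probe sets alone gave 1441 past 2-fold.

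In hmr-22, 16 of 22 polymerase and ribosome genes of the plastid rose and rpl33 fell, and 18 rose and 2 fell adjusted over the list alone. The largest rises were in rpoB (2.76 ± 0.19, adjusted p 0.00171), rpoC1 (2.69 ± 0.21, 0.00226), rps15 (2.44 ± 0.19), rpoC2 (2.41 ± 0.18) and rpl20 (2.31 ± 0.24), with rps2 at 2.01 ± 0.14 and the photosystem I assembly gene ycf3, which is in no list, at 1.92 ± 0.12. Wild type values of rpoB near the floor leave the size and rank of its rise uncertain here too. Of the 27 photosystem, cytochrome and rbcL genes none fell and 2 rose by both adjustments, petA (0.72 ± 0.12) and psaC (0.68 ± 0.12). The lowest value was that of psaJ (-0.96 ± 0.32, adjusted p 0.103, chosen after its values were seen), with each hmr-22 array below each wild type array. Changes in either direction within this list passed fry's mixed test (adjusted p 5.31e-06). The value of rbcL was -0.03 ± 0.14 (0.083 with median centring) and that of psbA -0.74 ± 0.30 (adjusted p 0.167, and 0.0458 with the replicate number as a block or 0.0463 among brighter probe sets). Of 16 atp and ndh genes 4 rose, ndhH (2.27 ± 0.19), atpH (0.92 ± 0.14), atpF (0.70 ± 0.15) and atpA (0.63 ± 0.14, adjusted p 0.0322, which rose to 0.139 under quantile normalization), and adjusted over the list alone 9 rose and 1 fell.

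Camera gave adjusted p of 2.35e-16 for the polymerase and ribosome list (median 1.21), 0.000128 for the atp and ndh list (median 0.49) and 0.495 for the photosystem list (median 0.0023, and -0.12 under quantile normalization). With an estimated correlation no list of this comparison passed (adjusted p = 0.139 and 0.603 with an estimated correlation for the former 2). The nuclear photosynthesis lists held no call over all probe sets on the deposited scaling: LHCB4.2 stood at 0.26 ± 0.11, LHCB4.1 at 0.23 ± 0.11 (both just under 0 with quantile normalization), PSAN at 0.32 ± 0.33 (-0.0076 without wild type replicate 3), PSBW at 0.30 ± 0.12, GSA1 at -0.48 ± 0.16 and CHLM at 0.45 ± 0.13. With median centring 2 tetrapyrrole genes rose, CHLM among them (adjusted p 0.0301). CHLM also passed with an intensity trend, both filters on dim probe sets and the added scale of log2 of the signal plus 32 (0.0176 to 0.0474), and GSA1 with the trend (0.0279) and among brighter probe sets (0.0242). Camera gave 0.252 for light-harvesting genes, 0.109 for other photosynthesis genes and 0.78 for tetrapyrrole genes. The medians of all 3 lists turn negative under quantile normalization. Adjusted over the list alone, 2 tetrapyrrole genes rose and 1 fell, and no gene passed in the other 2 lists. MRL7-L fell (-0.98 ± 0.18) by both adjustments. The light-signalling gene HYH stood at 0.63 ± 0.18 (adjusted p 0.0653) and passed adjusted over the list alone, where it stood by itself, as it did with the trend, median centring, both filters and the added scale (0.0118 to 0.0399).

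IAA29 (-1.33 ± 0.28, adjusted p 0.0265) and EXPA8 (-1.0 ± 0.20, 0.0229) fell in hmr-22 among 5 PIF-induced genes, and 3 fell adjusted over the list alone. IAA29 was at 0.0547 with the replicate number as a block. The camera adjusted p of 0.0409 rose to 0.0555 without wild type replicate 1, 0.137 without wild type replicate 2 and 0.0686 without hmr-22 replicate 1 (adjusted p = 0.461 with an estimated correlation). Of 8 cell wall genes EXPA8 fell, 2 fell adjusted over the list alone, and camera gave 0.077, which passed with median centring (0.0493), with log2 of the signal plus 32 (0.0487), without hmr-5 replicate 3 (0.048) and without hmr-22 replicate 3 (0.0397) (adjusted p = 0.603 with an estimated correlation and all arrays). Among auxin-inducible genes IAA29 fell and IAA20 rose (1.31 ± 0.26, from wild type values near the floor) by both adjustments, with camera 0.918. The largest falls among genes with a symbol were in CYP718 (at least 2.1-fold), ECS1 (-1.96 ± 0.45), GH9C2 (-1.90 ± 0.19), EXPB1 (-1.80 ± 0.15), CHIL (-1.79 ± 0.25), Hsp70-2 (-1.73 ± 0.18), PMEAMT (-1.61 ± 0.20), GH9B8 (-1.58 ± 0.19), and GSTU20 (-1.49 ± 0.29); GH9B17 passed with both means under the floor. Root markers EXPA7 (-1.34 ± 0.28) and EXPA18 (-1.15 ± 0.22) fell by both adjustments, with camera adjusted p 0.0409, which rose to 0.058 without wild type replicate 1, 0.091 without wild type replicate 2 and 0.0686 without hmr-22 replicate 1 (adjusted p = 0.396 with an estimated correlation).

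The glyoxylate cycle gene ICL and the leucine breakdown genes rose in hmr-22, with ICL at 2.47 ± 0.31, MCCA at 1.86 ± 0.24 and IVD at 1.34 ± 0.15, so both carbon starvation genes passed by both adjustments. GI (0.88 ± 0.14) and GID1A (0.87 ± 0.12) rose, and both gibberellin receptor genes passed adjusted over the list alone. NDB2 of the alternative respiratory chain fell (-0.81 ± 0.17), with 1 rise and 1 fall in the oxidative stress list adjusted over the list alone and camera 0.776. AUR1 (-0.51 ± 0.17) and AUR2 (-0.26 ± 0.19) did not pass, although 1 fell adjusted over the list alone and AUR1 passed among brighter probe sets (0.0289). AT4G14090 passed in the flavonoid list by both adjustments with both means under the floor (camera 0.918), a call lost in 7 of the other settings (0.0506 to 0.154). No call was made among stomatal genes (SPCH 0.63 ± 0.26, MUTE -0.55 ± 0.42, camera 0.918), the defence genes PDF1.2b (-0.03 ± 0.34) and PDF1.2 (both means under the floor) or OLEO3 (-0.36 ± 0.32), by either adjustment. Among genes known by a locus code only, AT4G37220 (2.56 ± 0.24) and AT1G19540 (2.54 ± 0.22) rose and AT2G23540 (-2.41 ± 0.27) and AT5G54370 (-2.36 ± 0.22) fell.

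Limma called 2352 probe sets between hmr-22 and wild type, 994 higher and 1358 lower, and 721 past 2-fold, 243 higher and 478 lower. With arrays centred on their medians 1619 were higher and 952 lower, or 63.0% higher against 42.3%, and the median of all probe sets shifted by 0.11. The share was 47.6% with quantile normalization and 44.6% with the 75th percentile. The count was 3660 with an intensity trend, 1067 with only these 2 genotypes and 613 with a minimum fold of 1.2, and 448 of the brighter probe sets passed 2-fold. It was 879 and 1426 without wild type replicates 1 and 3, and 1019, 777 and 1027 without hmr-22 replicates 1, 2 and 3; the 2-fold count fell to 433 without wild type replicate 1 and 439 without hmr-22 replicate 2. Of 40 named calls, 26 held in all 9 fits that leave out an array; ECS1, IAA29, EXPA8, IAA20, petA, psaC, atpF, atpA, MRL7-L, NDB2, EXPA7, EXPA18, GSTU20 and AT4G14090 did not (highest adjusted p 0.129). With only these 2 genotypes IAA29, IAA20, GSTU20, atpF, atpA, NDB2, EXPA18 and AT4G14090 lost their calls (0.0576 to 0.0773). With a minimum fold of 1.2 the 14 genes that did not hold with an array left out lost theirs (0.0548 to 0.193). The calls lost numbered 13, 6 and 7 without wild type replicates 1, 2 and 3, 2, 1 and 0 without those of hmr-5, and 7, 12 and 11 without those of hmr-22.

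The direct comparison of hmr-5 with hmr-22 asks where the alleles differ. Plastid photosystem genes set them apart: 11 of 27 were lower in hmr-5 and none higher, with psbC at -3.58 ± 0.21 (adjusted p 0.00106), rbcL at -3.27 ± 0.14 (0.000193), psbB at -3.0 ± 0.22 (0.00329), psbD at -2.97 ± 0.24 (0.00523), psbZ at -2.93 ± 0.16 and psbA at -2.79 ± 0.30 (0.0102). Adjusted over the list alone 17 were lower, the median was -0.86 and camera gave 6.3e-16 (adjusted p = 0.127 with an estimated correlation). By contrast rpoB differed by 0.06 ± 0.19 (adjusted p 0.904), and of the polymerase and ribosome list only rpl33 passed (-0.84 ± 0.18, adjusted p 0.041, and 0.0514 with the replicate number as a block), with 2 lower adjusted over the list alone and camera 0.0774, which passed without hmr-5 replicate 2 (0.0293) and without hmr-22 replicate 1 (0.00265). With all arrays it did not pass with an estimated correlation either (adjusted p = 0.523 with an estimated correlation).

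**Figure D2:**
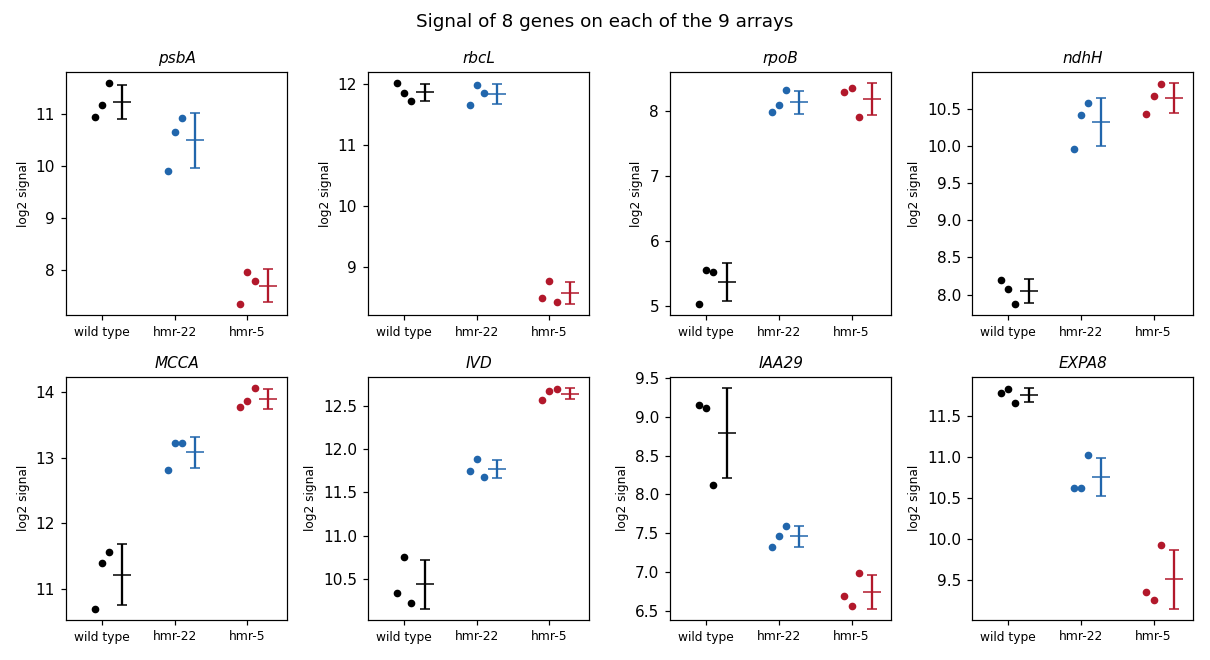
Log2 signal of 8 genes on each of the 9 arrays (points) with the mean and SD of each genotype (bars, n = 3). For psbA and rbcL the hmr-5 arrays lie far below the others, for rpoB and ndhH both mutants lie above wild type, and for MCCA, IVD, IAA29 and EXPA8 hmr-22 lies between wild type and hmr-5.

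Further plastid and chlorophyll genes were lower in hmr-5 than in hmr-22, which does not say which mutant departed from wild type. Against wild type ndhJ, ndhK, PORB and HEME2 fell in hmr-5, atpH rose in hmr-22 only, and HEME1 passed in neither. The median of other nuclear photosynthesis genes against wild type was -0.19 in hmr-5 and 0.17 in hmr-22 on the deposited scaling. Among 16 atp and ndh genes ndhJ (-1.48 ± 0.21), ndhK (-1.27 ± 0.19) and atpH (-0.76 ± 0.14) were lower, 5 were lower adjusted over the list alone, and camera gave 0.00126 (adjusted p = 0.511 with an estimated correlation). Of 9 tetrapyrrole genes PORB (-0.77 ± 0.12), HEME2 (-0.76 ± 0.15) and HEME1 (-0.59 ± 0.12, and 0.0539 with median centring) were lower, 7 adjusted over the list alone, with camera 0.000102 (adjusted p = 0.127 with an estimated correlation). Other nuclear photosynthesis genes held no call over all probe sets, SBPASE being at -0.65 ± 0.17 (adjusted p 0.0689, and 0.011 to 0.0459 with the trend, both filters, array weights and the added scale) and PSAN at -0.43 ± 0.33, but 6 of 8 were lower adjusted over the list alone and camera gave 0.000405 (adjusted p = 0.329 with an estimated correlation). Light-harvesting genes did not pass by either adjustment (LHCB4.1 -0.26 ± 0.11, LHCB4.3 -0.19 ± 0.10, camera 0.291).

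Of the growth genes EXPA8 was lower in hmr-5 (-1.25 ± 0.20, adjusted p 0.0217), XTH16 was lower (-1.04 ± 0.23, and 0.0571 with median centring) and EXPA4 higher (1.33 ± 0.20). That made 1 of 5 PIF-induced genes lower (2 adjusted over the list alone) and, in the cell wall list, 1 higher and 2 lower (1 with median centring) by both adjustments (camera 0.493). Camera gave 0.0504 for PIF-induced genes (adjusted p = 0.34 with an estimated correlation). It passed with centring on the median (0.0379) or 75th percentile (0.0484), among brighter probe sets (0.0115) and with log2 of the signal plus 32 (0.0366). It also passed without wild type replicate 3 (0.0118), hmr-5 replicate 3 (0.0182) or hmr-22 replicate 1 (0.0478). IAA29 (-0.72 ± 0.28) and GH3.3 (1.74 ± 0.61, and 0.0477 with the trend) did not pass, 1 auxin-inducible gene was higher adjusted over the list alone, and camera gave 0.381. IVD (0.88 ± 0.15) and GID1B (0.70 ± 0.16) were higher in hmr-5, with both members of their lists higher adjusted over the list alone. The largest differences toward hmr-5 among genes with a symbol were PDF1.4 (2.34 ± 0.32, adjusted p 0.0164), QQS (2.33 ± 0.24, 0.00974), the peroxidase gene PRX52 (2.22 ± 0.27) and the glycosyltransferase gene UGT73B4 (1.72 ± 0.28); GH9B17 also passed with both means under the floor. Among genes known by a locus code only, AT4G36430 (4.42 ± 0.16) and AT4G12490 (2.77 ± 0.23) were higher and AT1G60590 (-2.34 ± 0.23) and AT1G10850 (-1.78 ± 0.33) lower.

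The lists that remain gave no call between the alleles over all probe sets, except under the other settings given here. HYH was at -0.72 ± 0.18 and SPCH at -1.09 ± 0.26 (adjusted p 0.0608 and 0.0538), each passing adjusted over the list alone, and with the trend, the filter at a mean of 5, array weights and the added scale (0.0114 to 0.0455). MUTE gave no fold (camera 0.278 for stomatal genes). HYH passed among brighter probe sets too (0.0082). GI (0.33 ± 0.14) and AUR2 (-0.75 ± 0.19) passed adjusted over the list alone, AUR2 also with the trend, both filters, array weights and the added scale (0.0084 to 0.0422), and AUR1 (-0.40 ± 0.17) did not. Neither adjustment called MRL7-L (-0.32 ± 0.18) or AT5G15700 (at least 1.05-fold higher in hmr-22), STZ (0.56 ± 0.19) or GSTU25 (0.46 ± 0.40; camera 0.157), EXPA18 (0.27 ± 0.22) or EXPA7 (0.26 ± 0.28; camera 0.354), UGT78D2 (-0.20 ± 0.12; camera 0.772; no fold for AT4G14090), PDF1.2b (-0.04 ± 0.34; no fold for PDF1.2) or OLEO3 (-0.47 ± 0.32).

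Limma called 1174 probe sets between the alleles, 493 higher in hmr-5 and 681 lower, and 396 past 2-fold, 211 higher and 185 lower. With arrays centred on their medians 599 were higher and 463 lower, or 56.4% higher against 42.0%. The share was 47.4% with quantile normalization and 46.9% with the 75th percentile. The count was 2383 with an intensity trend, 2414 among the brighter probe sets, 328 with only these 2 genotypes and 132 with a minimum fold of 1.2. The count fell most without a mutant array: 84, 98 and 597 probe sets passed without hmr-5 replicates 1, 2 and 3. It was 141, 245 and 104 without hmr-22 replicates 1, 2 and 3, and 997, 766 and 908 without wild type replicates 1, 2 and 3. Past 2-fold there were 80 and 90 without hmr-5 replicates 1 and 2 and 115, 185 and 94 without hmr-22 replicates 1, 2 and 3. Of 27 calls of genes named for this comparison 10 held in all 9 such fits: psbC, rbcL, psbB, psbD, psbZ, psbA, QQS, AT4G36430, AT4G12490 and AT1G60590. Of 6 called genes named for another comparison 2 held, psbH and AT2G23540, and GH9B8, ATL8, AT1G19540 and AT5G50740 did not (0.0509 to 0.0757). With only these 2 genotypes 14 of the 27 lost their calls (0.052 to 0.0698): ndhJ, ndhK, atpH, rpl33, PORB, HEME1, HEME2, EXPA8, XTH16, GID1B, PDF1.4, UGT73B4, GH9B17 and AT1G10850, as did AT5G50740 (0.0564). With a minimum fold of 1.2 these other than ndhJ and PDF1.4 did, and EXPA4 and IVD (0.0586 to 0.263). GID1B was at 0.0508 with robust moderation and GH9B17 at 0.0663 with the trend. The calls lost numbered 1, 4 and 2 without wild type replicates 1, 2 and 3, 16, 15 and 6 without those of hmr-5, and 16, 14 and 17 without those of hmr-22, with a highest adjusted p of 0.142.

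The changes of the mutants against wild type were compared across genes, which are not independent replicates. Over 22746 probe sets the log2 fold changes correlated at r = 0.67, against a mean of 0.50 and a highest value of 0.54 in 100 simulations of unchanged groups sharing the wild type arrays. The covariance was 0.31 against a simulated 0.10. The simulations drew each array independently, without the pairing by replicate number. Higher in both mutants were 880 probe sets and lower in both 1157, where independent lists of those sizes would share 114.0 and 219.6. These expected numbers take no account of the shared wild type arrays. No split of 3 wild type arrays leaves 2 for each mutant, so none was made, and part of the agreement may come from the shared arrays. A single probe set, not named in the gene table and chosen after its values were seen, was lower in hmr-5 (-0.56 ± 0.18, adjusted p 0.0493) and higher in hmr-22 (0.81 ± 0.18, 0.0294). The moderated F test over the 3 genotypes called 5475 probe sets, 24.1% of those tested.

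**Figure D3:**
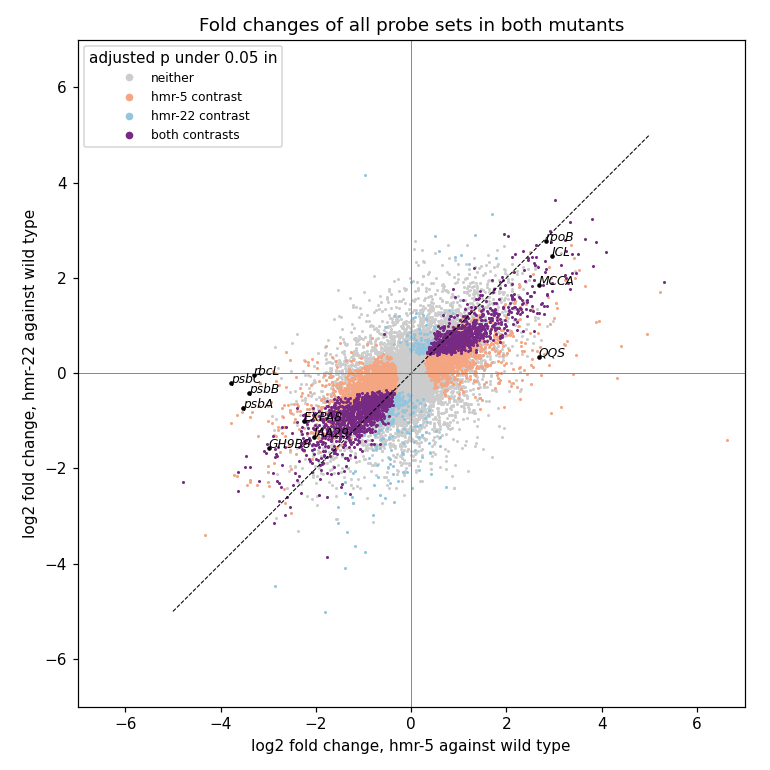
Log2 fold change of each of 22746 probe sets in hmr-5 (horizontal axis) and hmr-22 (vertical axis) against wild type, coloured by the comparison in which the adjusted p was under 0.05, with a dashed line of equal change. MCCA, ICL and rpoB lie at the upper right, EXPA8, IAA29 and GH9B8 at the lower left, and psbC, psbA, psbB and rbcL lie far to the left near the horizontal axis.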

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

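The tests of explanations and of other splits were chosen after the results were seen, and the comparison of the alleles was planned. The alleles' effects differed by the direct test in 4 gene lists, as medians of hmr-5 against hmr-22: -0.86 for plastid photosystem, cytochrome and rbcL genes, -0.46 for tetrapyrrole genes, -0.42 for other nuclear photosynthesis genes and -0.28 for plastid atp and ndh genes. Each passed camera with a preset correlation and none did with an estimated one, with which no list passed in any comparison.

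Of 95 named probe sets, 32 differed between the alleles with a fold to report, 12 of them higher in hmr-5. Many were named for large changes in these data, so this share is not that of all 22746 probe sets, of which 5.16% were called. Of 27 calls named for this comparison, GH9B17 without a fold among them, 10 held in all 9 fits that leave out an array. Of 6 named for another comparison 2 held. Lower in hmr-5 on the log2 scale were psbC (-3.58), rbcL (-3.27), psbB (-3.0), psbD (-2.97), psbZ (-2.93), psbH (-2.87), psbA (-2.79), ndhJ (-1.48), ndhK (-1.27), rpl33 (-0.84), atpH (-0.76), PORB (-0.77), HEME2 (-0.76), HEME1 (-0.59), GH9B8 (-1.41), EXPA8 (-1.25), XTH16 (-1.04), AT1G60590 (-2.34), AT1G10850 (-1.78) and AT5G50740 (-1.45). Higher in hmr-5 were AT4G36430 (4.42), AT4G12490 (2.77), AT2G23540 (2.43), PDF1.4 (2.34), QQS (2.33), PRX52 (2.22), UGT73B4 (1.72), AT1G19540 (1.55), ATL8 (1.38), EXPA4 (1.33), IVD (0.88) and GID1B (0.70). These values compare the alleles and do not say which of them departed from wild type. AT2G23540, for example, fell in hmr-22 against wild type, while its hmr-5 and wild type arrays overlapped.

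The plastid photosystem and rbcL transcripts were low in hmr-5. Array scaling as the whole cause is argued against by the list's median of -1.10 after quantile normalization, which makes the arrays' distributions alike. A smaller share of all plastid RNA that lowered every transcript alike would lower other plastid transcripts too. The polymerase, ribosome and housekeeping list had a median of 0.97, a value known when this test was chosen. It cannot exclude a lower total of plastid RNA alongside rises in that list. The alleles differed in this list by the direct test with camera at the preset correlation (adjusted p 6.3e-16), but not with an estimated one (adjusted p 0.127). Tested gene by gene, 11 of 27 were lower in hmr-5 than in hmr-22 and none higher. Of these psbC, rbcL, psbB, psbD, psbZ and psbA held in all 9 fits that leave out an array. The signals of these genes therefore differed between the alleles. A biological difference between the alleles stays open as the cause. RNA stability, the capture of plastid RNA by the labelling and the development of the seedlings were not tested.

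More probe sets were lower than higher in hmr-5, 3678 against 2608. The share of calls that were higher was 41.5% on the deposited scaling, 45.1% with centring on the 75th percentile, 48.9% with quantile normalization and 61.5% with centring on the median, which shifts all probe sets alike. Array scaling and a true imbalance cannot be told apart, since the scalings disagree. The poly-A spikes averaged 8.46 (SD 0.27) in wild type and 8.42 (SD 0.57) in hmr-5 on the log2 scale. The hybridisation spikes averaged 11.35 (SD 0.25) and 11.51 (SD 0.10). With such a spread over 3 arrays the spikes cannot decide on a shift of 0.18, the one made by median centring.

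Same-numbered arrays deviated together. The poly-A spikes added to the RNA were lowest on replicate 1 in all 3 genotypes, which chance gives with probability 0.111, so a shared labelling batch and a shared growth or harvest day cannot be told apart.

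Control probe sets of the plant's own genes, which entered no comparison, had every mutant array above every wild type array in 9 cases. The 25S ribosomal RNA control was 1.54-fold higher in hmr-5 and 1.31-fold in hmr-22. Ubiquitin controls were 1.33-fold and 1.26-fold higher for the 3' probe set, 1.27-fold and 1.22-fold for the second 3' probe set, and in hmr-5 also 1.19-fold, 1.55-fold and 1.15-fold for the 5', middle and second 5' probe sets. These folds are on the deposited scaling. Under quantile normalization the second 5' ubiquitin probe set stood at -0.0081 on the log2 scale in hmr-5, and in hmr-22 the 25S, 3' and second 3' ubiquitin probe sets shrank to 0.14, 0.045 and 0.043. Apart from the second 5' probe set the cases kept their direction under each scaling tried. In 15 cases, 7 in hmr-5 and 8 in hmr-22, every mutant array lay below every wild type array. These were actin and GAPDH controls, at 0.720-fold to 0.846-fold of wild type in hmr-5 and 0.744-fold to 0.785-fold in hmr-22, and in hmr-22 also the dim U12639 control, with the mutant mean under the floor. All 15 kept their direction under each scaling tried, the smallest being -0.059 on the log2 scale with median centring.

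Other splits of the arrays were counted. Among the 4 splits of 6 arrays that part every replicate number, the real one gave 1 result as large in each comparison, with 5030, 1067 and 328 calls (hmr-5 and hmr-22 against wild type, and hmr-5 against hmr-22, each fitted on 6 arrays) and at most 0 in the others; the remaining splits of the 10 gave at most 0, 1 and 1. So few splits cannot give a share under 0.05. Over the 3 genotypes, 1 of the 36 groupings that part every number, the real one with 5475 calls, was as large, the next giving 1062. A share of 1 in 36 is under 0.05 and is the smallest this test can give. The test was chosen after the results were seen, so chance is unlikely there but not excluded. Of 100 groupings drawn without regard to number the highest other gave 1715.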

How the results depend on the processing

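The scale of log2 of the signal plus 32 was chosen after the data were seen; the other settings were planned. The HMR level could not be computed under any of them. The replicate block gave 6728, 2623 and 956 probe sets for hmr-5 and hmr-22 against wild type and hmr-5 against hmr-22, 2331, 749 and 347 past 2-fold, and 5736 by the F test; beyond TBL41 in hmr-5, IAA29 and psbA in hmr-22 and rpl33 between alleles, it changed no named or list call. In the same order, the block kept 5885 of the main fit's 6286 calls, 2046 of 2352 and 783 of 1174. The trend gave 3660 for hmr-22 and 2383 between alleles. Fitting only the 2 genotypes compared gave 1067, 328 and, past 2-fold between alleles, 202. The brighter probe sets gave 1441 and 448 past 2-fold for hmr-5 and hmr-22, 2414 between alleles, and r = 0.83. A filter at a mean of 5 gave r = 0.76 and the added scale r = 0.78. A minimum fold of 1.2 gave 3374, 613 and 132. Fewer or brighter probe sets and a stricter null follow from how those settings are built; otherwise the cause was not tested.

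Leaving out 1 array gave 4450 to 5921 for hmr-5 (1989 to 2440 past 2-fold), 777 to 1966 for hmr-22 (433 to 729), 84 to 997 between alleles (80 to 376), 3660 to 4546 by the F test and r of 0.62 to 0.71.

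For lists the direction is that of the test. Directions that turned belonged to values not past the threshold in either setting. Under quantile normalization they were LHCB4.3 in hmr-5 (0.017), LHCB4.2 (-0.026) and LHCB4.1 (-0.014) in hmr-22, PDF1.2b (0.043, 0.022 and 0.021 in the 3 comparisons), the light-harvesting list in hmr-5 (0.017) and, in hmr-22, the lists of other photosynthesis (-0.077), tetrapyrrole (-0.076) and plastid photosystem genes (-0.12). Median centring turned LHCB4.3 (0.031), HYH (0.083) and PDF1.2b (0.11) in hmr-5, PDF1.2b (0.083) and rbcL (0.083) in hmr-22, PDF1.2b between alleles (0.026) and the test of the flavonoid list in hmr-22 (median 0.32). Array weights turned PDF1.2b in hmr-22 (0.078) and the added scale PDF1.2 in hmr-5 (0.00273). The test direction of the flavonoid list turned with the block and with fry (medians 0.00259 in hmr-5 and 0.20 in hmr-22), and fry turned the stomatal list in hmr-22 (-0.16). List medians also turned where the test did not: light-harvesting genes in hmr-5 with median (0.15) and 75th percentile centring (0.0014), oxidative stress genes in hmr-5 with median centring (0.038), and in hmr-22 light-harvesting genes with quantile normalization (-0.014), auxin genes with the filter (-0.037) and plastid photosystem genes among brighter probe sets (-0.015).

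With 1 array left out, the values of genes and the tests of lists that turned are given here with the range of the value or median. In hmr-5 these were PDF1.2 (-0.89 to 0.64), PDF1.2b (-0.22 to 0.15), the flavonoid list (-0.10 to 0.068) and the oxidative stress list (-0.36 to 0.073). In hmr-22 they were PSAN (-0.0076 to 0.52), PDF1.2 (-1.64 to 0.23), PDF1.2b (-0.33 to 0.30), rbcL (-0.11 to 0.054), and the auxin (-0.43 to 0.11), flavonoid (0.16 to 0.26) and stomatal (-0.33 to -0.074) lists. Between alleles they were PDF1.2 (-0.52 to 1.64), PDF1.2b (-0.37 to 0.25), rpoB (-0.027 to 0.19), and the flavonoid (-0.17 to 0.38) and cell wall (-0.34 to 0.12) lists. Medians alone turned for light-harvesting genes in hmr-5 (-0.063 to 0.011) and for tetrapyrrole (-0.084 to 0.20) and plastid photosystem genes (-0.041 to 0.074) in hmr-22. List medians, means and tests differed in sign for flavonoid genes in both mutants, light-harvesting and oxidative stress genes in hmr-5, and auxin and stomatal genes in hmr-22.

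Fry, which tests a list by itself and not against other genes, passed where camera did not for other photosynthesis (adjusted p 0.0226), tetrapyrrole (0.00115), cell wall (0.0251), root marker (0.0148) and stomatal genes (0.0351) in hmr-5, and for PIF-induced (0.0297), oxidative stress (0.0395) and stomatal genes (0.0428) between alleles. Among lists that passed camera, only atp and ndh genes between alleles did not pass fry (0.0597). Fry passed for the rest, with 7.44e-05 for plastid photosystem genes between alleles. In hmr-5 it gave 6.55e-05 for the plastid photosystem list and for the polymerase and ribosome list.

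Of 2095 named-gene values under other settings, 1972 kept direction and side of the threshold, 73 lost and 36 gained a call; of 1494 with 1 array left out, 1300, 174 and 5 did. For lists the numbers were 373, 12 and 16 of 411, and 323, 8 and 8 of 351. Probe sets with a log2 mean below 5 had a median SD of 1.06 within genotypes, and those above 10 had 0.15.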

Other observations

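The families and the test of neighbouring genes were chosen after the data were seen. Genes were grouped by the letters that open their symbols, and the families with at least 8 measured genes, with the mitochondrial genome as a further group, were tested with camera. Between the alleles the UDP-glycosyltransferase family (UGT), enzymes that attach sugars to small molecules, was the only family past the threshold on the deposited scaling: of 47 measured genes 3 were higher in hmr-5 (UGT73B4, UGT73B1 and UGT87A2) and none lower, with a median of 0.27 and adjusted p 0.0337 (adjusted p = 0.849 with an estimated correlation). The call was lost with median centring (adjusted p 0.0544). Against wild type 11 of these genes rose and 3 fell in hmr-5 (adjusted p 0.0709), and 2 rose and 3 fell in hmr-22 (0.736).

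Families that stayed over the threshold in hmr-5 (adjusted p 0.0709 for each) included the glycosyl hydrolase and GH3 genes grouped under GH, of which 5 of 19 fell, the IQD genes, of which 5 of 15 fell, and the aldehyde dehydrogenase genes, of which 5 of 8 rose and 2 fell. In hmr-22 the GH genes (5 fell, adjusted p 0.0885) passed with median centring (0.0399; adjusted p = 0.399 with an estimated correlation). Of 23 mitochondrial genes 2 rose in hmr-5, nad5 and ccb382, and 1 in hmr-22, with medians of 0.23 and 0.26 and adjusted p 0.212 and 0.166. These family medians kept their direction under each scaling tried.

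A hypothesis was that plastid genes next to each other change together, as shared transcription units would make them. Taking 65 list genes in the order of the plastid genome, the mean absolute difference in log2 fold change between 64 neighbouring pairs was 1.12 in hmr-5, 0.595 in hmr-22 and 0.66 between the alleles. Reordering genes within their lists 100000 times gave means of 1.60, 0.90 and 0.86, with one-sided permutation p adjusted over the 3 comparisons of 0.00012, 3e-05 and 0.00432, where the raw p in hmr-22 is the smallest the reorderings can give. Neighbours therefore changed more alike than list membership alone accounts for, which is consistent with shared transcription units, and gene order was not tested against other causes such as the strand or RNA processing.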
